A study of Homo sapiens with 3 samples.

How the data were processed

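Total RNA was extracted with TRIzol from HCT116 cells carrying a lentiviral MYOD1, PPARG or empty-vector construct, and libraries were made with an NEBNext Ultra RNA kit, per the labels' protocols. The samples were assigned to 3 groups of 1 library from the labels, which give a culture time of 11 days. Whether poly(A) RNA was selected is not given in the sources used here.

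The authors deposited 1 table of FPKM, reads scaled to gene length in kilobases and to a library total, for 61802 features with gene names, positions, strands, biotypes and gene lengths. CASAVA, HISAT2 and featureCounts version 1.5.0-p3 were used with the genome build GRCh38, per the submitters' processing notes. The annotation release, the use of strand in counting, the treatment of reads that match several genes and the origin of the library scaling totals are not given in the sources used here. Coordinates are as deposited, and GENCODE release 29 served only for transcript GC content and for the overlap of exons.

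Multiplied by gene length, 100% of the FPKM values of each library were whole multiples of 1 step within 0.05 reads, so that read numbers could be recovered up to that step. The recovered reads summed to 17000174 in the control, 17614500 in the MYOD1 and 17525932 in the PPARG library. The library totals by which the deposited FPKM had been scaled came out at 18960721, 16750996 and 16151942, which is 1.12, 0.951 and 0.922 times the recovered reads, so the choice of scale bears on every ratio. At these depths 1 read on a gene of 1 kb is worth 0.0527, 0.0597 and 0.0619 FPKM.

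The 250 unnamed loci in the table, which held 0.220%, 0.167% and 0.347% of reads, were left out of the comparisons, and 12448 of the 61552 named genes, 10617 of them protein-coding, had an FPKM of at least 1 in at least 1 library and were compared. Log2 ratios were taken of FPKM plus a pseudocount of 1. With 1 library per group there was no test, p-value or standard error. Genes were counted by size, at 4-fold or more on that scale, in MYOD1 against control, PPARG against control and MYOD1 against PPARG. Each fold printed is a ratio of FPKM with an exact conditional Clopper-Pearson interval at 95% from the recovered reads. It covers counting error only and compares these libraries, not the conditions. Against 0 reads the fold is a lower bound from a floor of 3 reads per library.

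The 37 gene lists, with 1067 genes of which 1055 were in the table and 756 could be compared, the rule for named genes, the thresholds and the first set of alternatives were fixed before the data were examined. A list median was placed among the medians of 10000 random lists of the same size matched on mean log2(FPKM + 1) in 20 bins, as a description of these libraries, for lists with at least 3 measured members. The genes named are MYOD1 and PPARG, the 10 highest and 10 lowest protein-coding log2 ratios to the control, the 5 highest and 5 lowest of MYOD1 against PPARG, and from each list up to 4 members with the largest log2 ratios of at least 2-fold, or the 2 with the highest mean FPKM where no member reached 2-fold. This rule names 255 genes, of which the text gives a part, and the results of some of them are not reported here. Genes and families named outside the rule are said to have been chosen after their values were seen.

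The alternatives fixed in advance were a pseudocount of 0.1 or 5, no filter on low values, a minimum FPKM of 5, FPKM rescaled to TPM (the same sum in every library), median-of-ratios scaling, protein-coding genes only, a 2-fold threshold and counting intervals wholly beyond 2-fold. Scaling to the recovered reads, subtraction of the running median of log2 ratios over gene length, alone or with transcript GC content, in 20 bins each, and random lists matched also on gene length were added after seeing the data.

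Among the 255 genes, ALDOA and SRSF1 had at least 50% of their exonic bases covered by exons of other genes, at 53.5% and 60.7%. The share was 35.8% for KLHL41, and for PLAU, ANKRD37, LYZ and ACTA2 it was 31.1%, 35.2%, 33.96% and 30.1%, there on the opposite strand, whose reads cannot be set apart without knowledge of strand use. Histones, keratins, HLA class I genes, CEACAM genes and ribosomal proteins have near-identical copies or pseudogenes, and their values are uncertain to that extent.

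The scripts were tested on simulated counts that varied by counting error alone, with 200 genes changed by known folds. With 11361 genes in MYOD1 against control, 11389 in PPARG against control and 11374 in MYOD1 against PPARG, 73.1%, 83.8% and 72.1% of the genes changed 8-fold passed the 4-fold size rule. Of genes changed 4-fold 0%, 0% and 4.48% passed it, and of unchanged genes 0, 0 and 4. Counting intervals held the true fold for 95.6%, 95.5% and 95.3% of genes, and 4, 6 and 4 of 100 unchanged random lists lay outside the central 95%. These numbers do not bear on variation between libraries. Unchanged libraries were also simulated with an assumed coefficient of variation of 0.4. Of 12448 genes, means of 40.8 then passed the 4-fold rule as higher and 40.6 as lower in MYOD1 against control. In PPARG against control the means were 40.7 and 40.1. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 were used.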

Results

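RNA was sequenced from HCT116, a human colon cancer cell line of epithelial origin, carrying lentiviral constructs for forced expression of 1 of 2 transcription factors or the empty vector. MYOD1 is the transcription factor that sets off the skeletal muscle program, and PPARG is the nuclear receptor that drives adipocyte formation and lipid storage. Cells were cultured for 11 days before collection, and each of the 3 groups holds 1 library. The data address how the transcriptome of cells carrying each factor differed from that of cells carrying the empty vector. With 1 library per group no difference had a replicate check, and no p-value was computed.

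Over all features, the FPKM table held 17000174 reads in the control library, 17614500 in the MYOD1 library and 17525932 in the PPARG library, as recovered from FPKM and gene length. The comparisons ran on 12448 named genes with an FPKM of at least 1 in at least 1 library. Log2 ratios are of FPKM + 1, which understates the ratio of low genes. Folds are ratios of FPKM, followed in brackets by an exact 95% interval from the recovered reads, which covers counting error only. Genes counted as higher or lower differed by at least 4-fold on the log2(FPKM + 1) scale, and members of gene lists by at least 2-fold.

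The forced genes were read first in every library. MYOD1 (ENSG00000129152, GRCh38 chromosome 11, 17719571 to 17722136, plus strand) stood at 979 FPKM in the MYOD1 library and had no read in the control or the PPARG library. PPARG (ENSG00000132170, GRCh38 chromosome 3, 12287368 to 12434356, plus strand) stood at 2.66 FPKM in the control library, 1.97 in the MYOD1 library and 66.7 in the PPARG library, where it was 25.03-fold [23.1 to 27.2] higher than in the control. FPKM divides the PPARG reads by a gene length of 11981 bases, and the values do not separate reads of the construct from those of the cell's own gene.

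**Figure D1:**
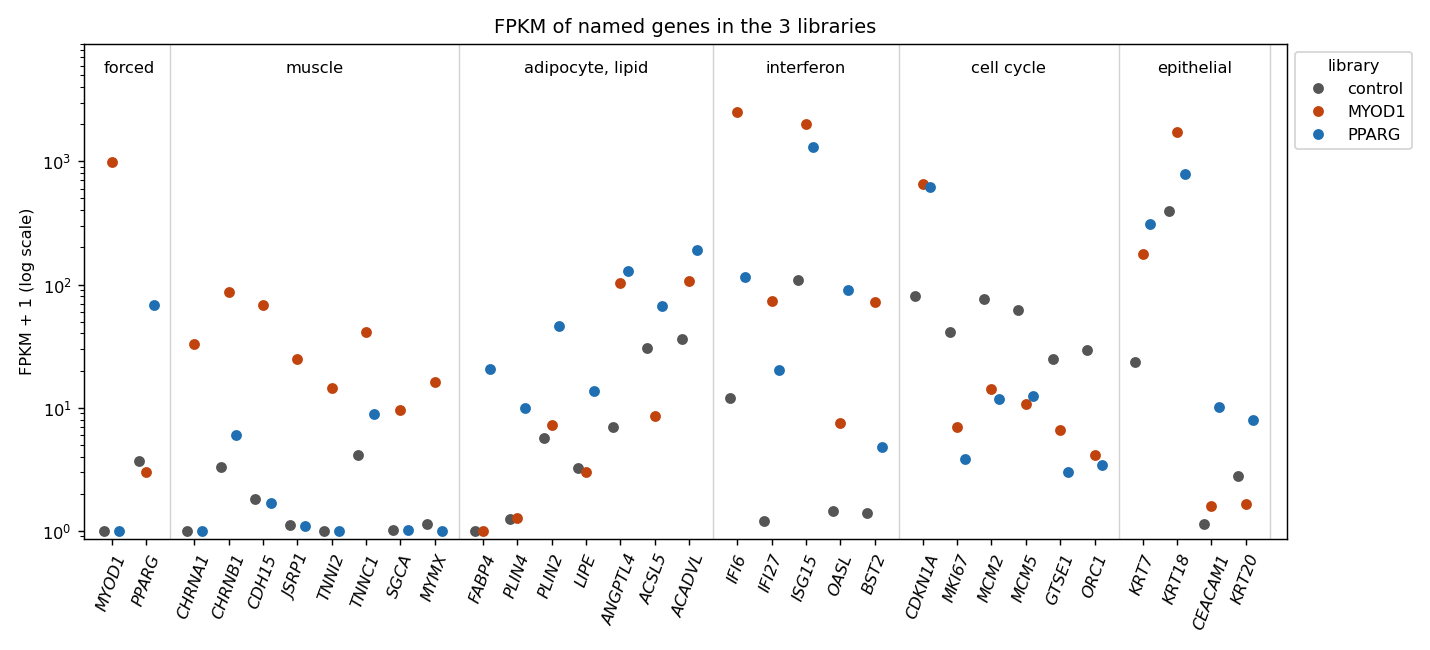
FPKM + 1 on a log axis for named genes in the control, MYOD1 and PPARG libraries, 1 point per library with no replicates. MYOD1 stood at 979 FPKM in its own library and at 0 in the others, FABP4 at 19.7 FPKM in the PPARG library and at 0 in the others, and MKI67 at 39.8 FPKM in the control against 5.98 and 2.82 FPKM.

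Genes of skeletal muscle were higher in the MYOD1 library than in the control library. Among them were subunits of the muscle acetylcholine receptor, with CHRNA1 (chromosome 2, 174747592 to 174787935) at least 1002-fold higher at 31.8 against 0 FPKM and CHRNB1 37.6-fold [32.5 to 43.7] higher. The muscle cadherin CDH15 was 83.9-fold [66.4 to 108] higher. The sarcoplasmic reticulum protein JSRP1 was 220.2-fold [85.6 to 810.0] higher, the myoblast fusion protein MYMX 123-fold [33.7 to 1025] and the sarcoglycan SGCA 496-fold [88.5 to 19626], with 4 reads or fewer in the control for the last 3. Of the 14 measured genes of muscle membrane, calcium handling and metabolism, 8 were at least 2-fold higher and 0 lower, with myoglobin (MB) among them at 43.9-fold [24.3 to 88.7]. Of the 16 measured sarcomere genes 10 were higher, including the troponins TNNI2 (at least 91.7-fold), TNNC1 at 12.7-fold [9.88 to 16.5] and TNNT1 at 3.74-fold [3.56 to 3.94], and the sarcomere-associated KLHL41 at 189-fold [33.5 to 7510.4]. Of the 11 measured muscle regulators 6 were higher, with BIN1, a gene of transverse tubules, at 4.16-fold [3.90 to 4.44]. The other 5, named after their values were seen, had log2 ratios of 0.68 (SIX4), 0.61 (MEF2D), -0.09 (SRF), -0.36 (MEF2A) and -0.48 (MEF2C). The list medians were 1.499, 1.22 and 1.20 on the log2 scale, at percentiles 100, 100 and 99.94 of 10000 random lists matched on size and mean expression. With genes without a read in 1 library set at their bound, the sarcomere median was 1.31. Most genes of these lists stayed under 1 FPKM in every library, so that 16 of 52 sarcomere genes and 11 of 25 regulators could be compared. The regulator median was 0 when unexpressed members were kept, here meaning those under 1 FPKM in every library, some of which had reads. The regulators MYOG, MYF5 and MYF6, chosen after their values were seen, had no read in any library. Among others chosen in this way, the skeletal actin ACTA1 stood at 0.0665 FPKM in the control and 0.0251 in the MYOD1 library. The embryonic myosin MYH3 stood at 0.0710 and 0.0715 and the muscle creatine kinase CKM at 0.0339 and 0.115, from 9 reads or fewer each.

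Measured mesenchymal and matrix genes were also higher in the MYOD1 library, 7 of 10 by at least 2-fold. The list median was 1.41 at percentile 99.98. The higher genes included the transcription factor SNAI2 at 366-fold [101 to 3025], S100A4 at 3.96-fold [3.84 to 4.09] and the collagen COL6A2 at 3.64-fold [3.48 to 3.80]. S100A4 was higher still in the PPARG library, at a log2 ratio of 2.47 against 1.98, and SNAI2 and COL6A2 stood at 0.49 and 0.20 there. In that library 3 of the 10 were at least 2-fold higher and 0 lower. Of the 34 genes listed, only these 10 reached 1 FPKM in a library. Chosen after their values were seen, FN1 had a log2 ratio of -0.31 in the MYOD1 library, against 9 positive ones. Also chosen in this way, VIM stood at 0.0713 FPKM in the control and 0.473 in the MYOD1 library, and CDH2, CDH11 and COL1A2 had no read. Of the 7 measured smooth muscle genes 3 were higher, among them PDLIM3 at 18.3-fold [14.7 to 23.2] and ACTA2 at 9.21-fold [5.90 to 15.1], and the median of 0.56 lay at percentile 89.19.

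Interferon-stimulated genes, the genes that cells switch on after interferon or viral RNA, were the list that stood farthest above the control. All 25 measured members had a positive log2 ratio and 22 were at least 2-fold higher, with a median of 2.02. IFI6 was 229-fold [199 to 265] higher, at 10.99 against 2516 FPKM, IFI27 358-fold [220.4 to 627], BST2 185-fold [93.5 to 429] and ISG15 18.7-fold [17.8 to 19.6].

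The highest log2 ratios of protein-coding genes included those of C6orf15 (at least 2750.2-fold, at 376 FPKM and no read in the control), IFI6 and the sphingosine-1-phosphate transporter SPNS2 (358-fold [291 to 446]). They were followed by the secreted glycoprotein PAEP (at least 1109-fold), the kallikrein protease KLK5 (210.3-fold [140.0 to 332]), and the calcium-binding CALB2 (224-fold [138 to 392]). LCN2 (164-fold [106 to 268]), IFI27 and the urokinase PLAU (66.9-fold [61.3 to 73.1]) were also among the 10 highest.

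Genes of cell division were lower in the MYOD1 library. Of 41 measured S phase genes 33 were at least 2-fold lower and none higher, with a median of -1.40, and of 51 G2 and M phase genes 27 were lower and none higher, with a median of -1.02. Both medians lay below those of all 10000 random lists. The replicative helicase subunits MCM5 and MCM4 were 6.31-fold [5.94 to 6.72] and 6.004-fold [5.69 to 6.34] lower, ATAD2 8.61-fold [7.59 to 9.80] and DTL 8.41-fold [7.03 to 10.1], and the proliferation marker MKI67 (chromosome 10, 128096659 to 128126423) 6.67-fold [6.29 to 7.07].

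Members of the p53 target list were higher, 11 of 24 by at least 2-fold against 1 lower. The cyclin-dependent kinase inhibitor CDKN1A, which is in both this and the next list, stood at 8.36-fold [8.10 to 8.63], GDF15 at 7.44-fold [7.29 to 7.59] and GADD45A at 4.68-fold [4.37 to 5.01]. Of 15 cell cycle inhibitors and pocket proteins 9 were higher and 1 lower, with CDKN1C at 9.30-fold [8.09 to 10.7] and GADD45B at 6.40-fold [5.44 to 7.56]. These list medians were 0.69 and 1.52, at percentiles 98.89 and 100.

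Ribosome biogenesis and spliceosome genes had lower medians. Of 39 ribosome biogenesis genes 15 were at least 2-fold lower and none higher (median -0.93), with HEATR1 6.69-fold [5.93 to 7.56] and UTP20 8.14-fold [6.82 to 9.78] lower. Of 43 spliceosome genes 15 were lower (median -0.71), led by SRSF1 at 7.49-fold [6.55 to 8.60], a gene of which 60.7% of the annotated exonic bases overlap other genes. Chromatin repressors (10 of 30 lower, median -0.59) included UHRF1, which is also in the S phase list, at 3.88-fold [3.64 to 4.14] and the DNA methyltransferase DNMT1 at 3.79-fold [3.62 to 3.96]. Of 25 cholesterol synthesis genes 7 were lower and 2 higher (median -0.63), with SQLE 3.39-fold [3.09 to 3.72] lower and TM7SF2 3.63-fold [3.31 to 3.99] higher. Proteasome genes had a median of -0.38 with 4 of 31 lower. Heat shock genes had one of -0.51 with 5 of 12 lower, including the chaperonin HSPD1 at 4.05-fold [3.91 to 4.19], and HSPB1 2.48-fold [2.42 to 2.54] higher. The percentiles of these 6 medians were at most 0.3. Fatty acid synthesis genes had a median of -0.65 at percentile 0.06, with FASN 3.07-fold [3.03 to 3.11] and SCD 2.92-fold [2.87 to 2.98] lower. After correction for gene length and GC content the median was -0.25, within the central 95% of random lists.

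Hypoxia genes were higher, 10 of 18 with a median of 1.54, among them ANGPTL4, also a member of the PPAR target list, at 17.1-fold [15.1 to 19.4], the glucose transporter SLC2A1 at 5.54-fold [5.37 to 5.72] and NDRG1 at 5.04-fold [4.80 to 5.29]. Of 7 measured replication-dependent histone genes 4 were higher (median 1.68), led by H2BC5 at 15.6-fold [10.5 to 24.2], though near-identical histone copies can share reads. These medians lay at percentiles 100 and 99.98, the second within the central 95% when unexpressed members were kept.

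Single genes of other lists stood apart where the list as a whole lay within the central 95% of random lists. In the Wnt and stem cell list (6 of 15 higher, 2 lower) the Wnt antagonist DKK1 was 22.6-fold [19.6 to 26.4] lower, the lowest log2 ratio of all protein-coding genes compared. MYC was 4.46-fold [4.24 to 4.69] lower and the Wnt deacylase NOTUM 14.7-fold [12.96 to 16.8] higher. The progenitor filament NES was 24.5-fold [22.5 to 26.7] higher, the Notch modifier LFNG 9.999-fold [8.76 to 11.5], the transcription factor JUN 16.9-fold [15.3 to 18.7], the glucose transporter SLC2A3 28.4-fold [23.3 to 34.9] and the neuronal enolase ENO2 4.57-fold [4.29 to 4.88]. Of 37 epithelial genes 14 were higher and 2 lower, with KRT7 at 7.86-fold [7.47 to 8.28] and KRT18 at 4.41-fold [4.34 to 4.47]. Of 16 adipocyte markers 4 were higher and CAV1 was 5.16-fold [4.84 to 5.51] lower. Their median was 0.42, or 0.58 with bounds, at percentile 84.43. Further protein-coding genes with the lowest log2 ratios were the vitamin D hydroxylase CYP24A1 at 16.6-fold [13.2 to 21.2], ITPRID2 at 7.65-fold [7.27 to 8.04], and the replication origin gene ORC1 at 8.91-fold [7.59 to 10.5]. KITLG at 7.67-fold [7.14 to 8.25], SFPQ at 6.93-fold [6.53 to 7.37], MKX at 13.9-fold [10.3 to 19.2] and the transporter ABCC2 at 8.001-fold [7.13 to 9.004] were among them too.

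In all, 384 genes were at least 4-fold higher and 73 at least 4-fold lower in the MYOD1 library. That balance depended on the scaling, with 469 higher and 681 lower when FPKM was rescaled to TPM, which moves the median of all genes by -0.43, and 289 higher and 145 lower on the recovered reads, which moves it by -0.18. The 20 of 36 list medians outside the central 95% of random lists stayed outside it under all 3 other scalings.

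**Figure D2:**
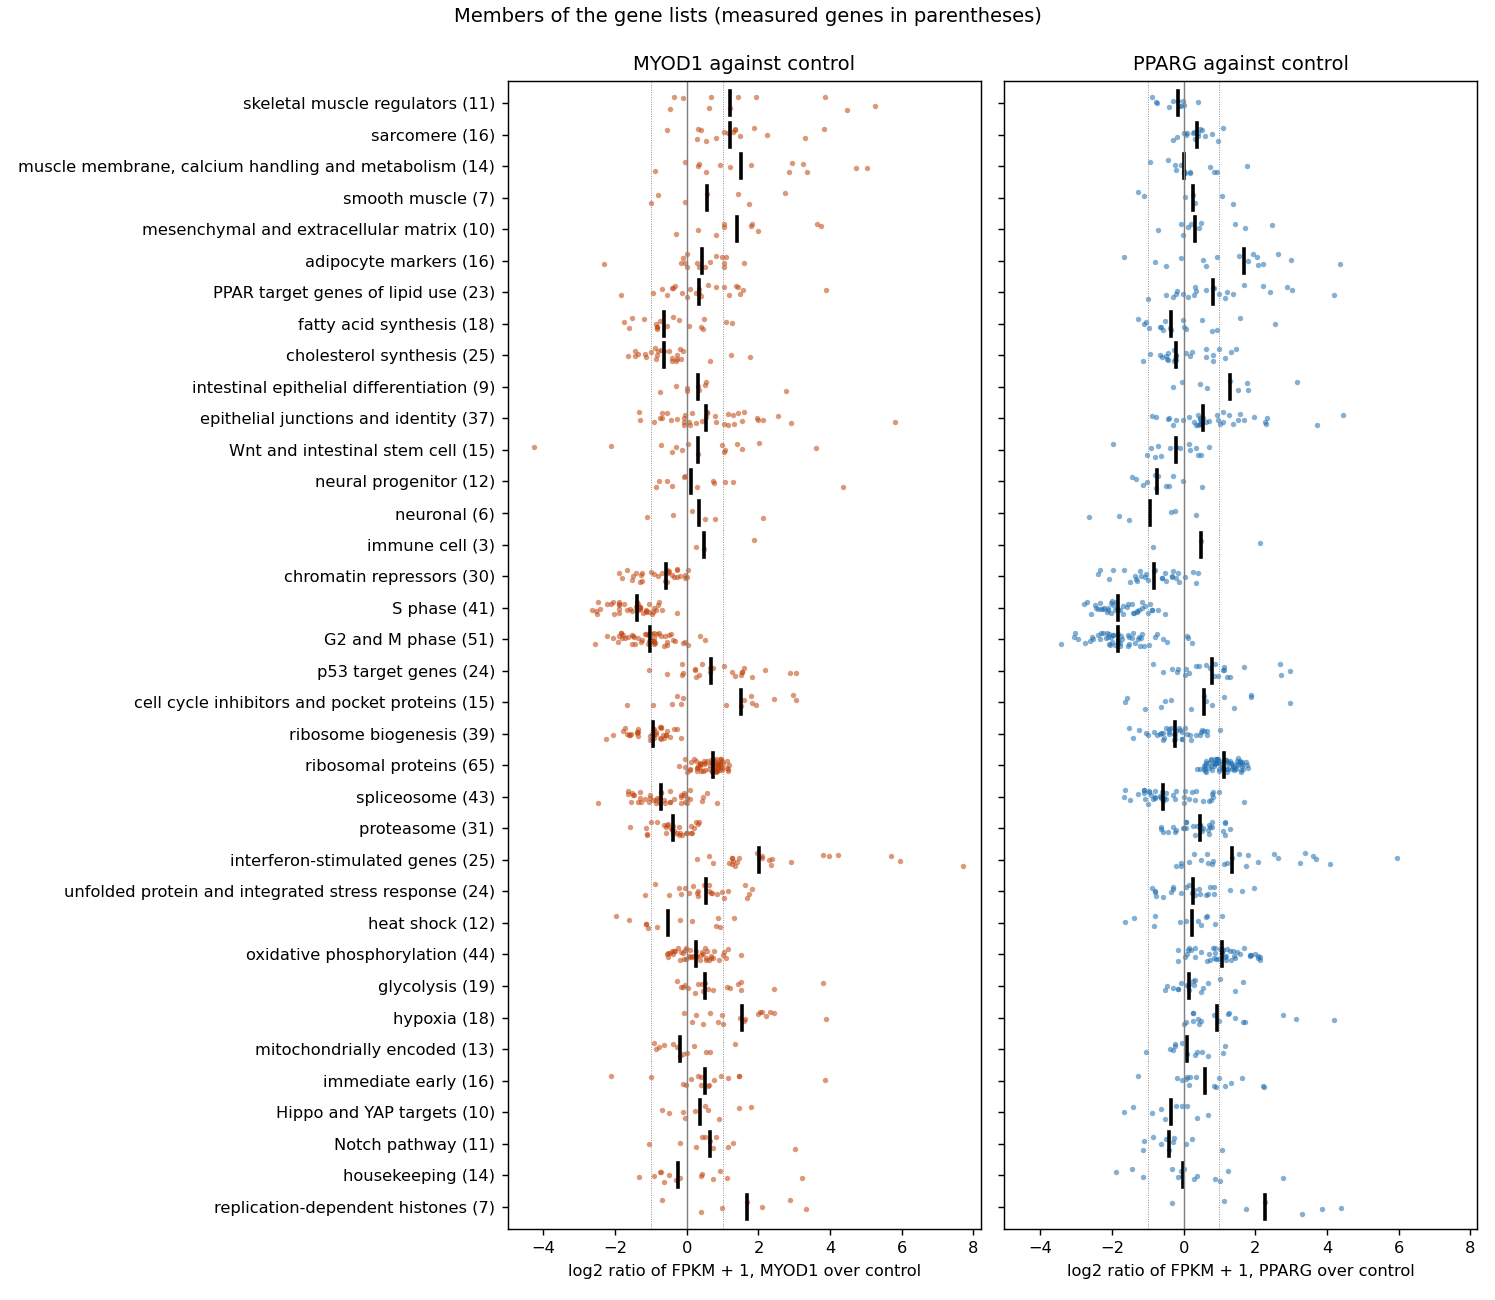
Log2 ratio of FPKM + 1 for each measured member (points) of the gene lists in the MYOD1 library (left) and the PPARG library (right) over the control library, with the list median as a black bar and dotted lines at 2-fold. The S phase medians lie at -1.40 and -1.82 and the interferon medians at 2.02 and 1.34, while the muscle membrane list lies at 1.499 in the MYOD1 library and the adipocyte list at 1.67 in the PPARG library.

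Adipocyte and lipid-use genes were higher in the PPARG library than in the control library. The fatty acid carrier FABP4 (chromosome 8, 81478419 to 81483236) stood at 19.7 FPKM against no read in the control, at least 170.2-fold higher. The lipid droplet protein PLIN4 was 35.7-fold [24.96 to 52.8] higher, the acyltransferase AGPAT2 6.25-fold [5.97 to 6.54] and the triglyceride lipase PNPLA2 4.78-fold [4.55 to 5.04]. Of 16 measured adipocyte markers 9 were at least 2-fold higher and 1 lower, with a median of 1.67 above those of all 10000 random lists. Of 23 PPAR target genes of lipid use 9 were higher and 1 lower, with a median of 0.81 at percentile 99.88. They included the lipase inhibitor ANGPTL4 at 21.3-fold [18.8 to 24.1], the lipid droplet protein PLIN2 at 9.64-fold [8.73 to 10.7], the acylcarnitine carrier SLC25A20 at 9.09-fold [7.62 to 10.9] and the fatty acid oxidation enzyme ACADVL at 5.45-fold [5.24 to 5.66]. In the MYOD1 library 7 of these 23 genes were also higher and 1 lower. There the log2 ratios were 3.89 for ANGPTL4, 1.57 for ACADVL, 1.44 for SLC25A20 and 0.34 for PLIN2. Of the adipocyte markers named here, they were 1.59 for AGPAT2, 0.97 for PNPLA2, 0.01 for PLIN4 and 0 for FABP4.

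Of the 38 adipocyte genes listed, 16 reached 1 FPKM in a library, and the adipocyte median was 0 when unexpressed members were kept. Chosen after their values were seen, the lipid droplet protein PLIN1 stood at 0.0139 FPKM in the control and 0.0816 in the PPARG library. The glycerol channel AQP7 went from no read in the control to 70 reads, or 0.825 FPKM, in the PPARG library. Also chosen in this way, ADIPOQ, LPL, PCK1 and G0S2 had no read in any library. CD36, of the PPAR target list, had 4 reads in the control and 0 in the PPARG library.

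Intestinal differentiation genes were higher too, 5 of the 9 measured, with CEACAM1 at 72.96-fold [42.4 to 138], CEACAM5 (at least 63.00-fold), CEACAM6 (at least 45.00-fold) and the keratin KRT20 at 3.91-fold [2.94 to 5.25]. CEACAM6 was higher still in the MYOD1 library, at a log2 ratio of 2.76 against 1.77. The list median was 1.29, or 1.51 with genes without a read in the control at their bound, above those of all random lists. It was 0.61 after correction for gene length and GC content, outside the central 95%, and 0 when unexpressed members were kept. With members of at least 5 FPKM alone it lay within the central 95%. Of the 38 genes listed, only these 9 reached 1 FPKM in a library. Chosen after their values were seen, KLF4, CDX2, HNF4A and CA2 had log2 ratios of 0.65, 0.45, -0.03 and -0.30. Also chosen in this way, FABP1, FABP2, ALPI, SI, CDX1 and SLC26A3 had no read in any library. Of 37 epithelial genes 14 were higher and none lower (median 0.53, percentile 74.14), with KRT7 at 13.9-fold [13.2 to 14.6].

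The highest log2 ratios of protein-coding genes included those of the calcium-binding S100P at 555-fold [153 to 4587], with 2 reads in the control, the interferon-induced OASL at 198-fold [152 to 264] and the protease inhibitor SLPI at 87.1-fold [60.1 to 131]. Next came C11orf86 at 673-fold [186 to 5566], IGFL2 at 269-fold [149.9 to 539] and SDCBP2 at 113-fold [78.9 to 168]. The histone H2BC5 at 33.7-fold [22.8 to 51.98], FABP4 and ANGPTL4 were also among the 10 highest.

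Genes of cell division were lower in the PPARG library as well. Of 41 S phase genes 35 were at least 2-fold lower and of 51 G2 and M phase genes 43, with none higher in either list, and the medians were -1.82 and -1.83, below those of all random lists. MKI67 was 14.1-fold [12.99 to 15.4] lower, the condensin subunit NCAPD2 9.20-fold [8.60 to 9.84], GTSE1 11.8-fold [9.93 to 14.2], CDCA2 17.5-fold [12.8 to 24.5] and MCM2 6.95-fold [6.46 to 7.48]. The p53 target list had 9 of 24 members higher and none lower (median 0.80, percentile 99.09), with CDKN1A at 7.88-fold [7.63 to 8.13], TP53I3 at 8.27-fold [6.92 to 9.94] and PHLDA3 at 6.85-fold [6.35 to 7.39]. Among cell cycle inhibitors and pocket proteins 5 of 15 were higher and 3 lower, including the pocket protein RBL1 at 9.29-fold [6.50 to 13.7], and the median of 0.57 lay at percentile 96.28.

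Genes of the chromatin repressor list were lower (13 of 30, median -0.82), with DNMT1 at 5.66-fold [5.37 to 5.98], CBX5 at 5.42-fold [4.92 to 5.99] and AURKA at 4.78-fold [4.22 to 5.42]. CBX5 and AURKA are also in the G2 and M phase list and UHRF1 in the S phase list, so these results overlap. Spliceosome genes had a median of -0.57 with 8 of 43 lower, including PRPF8 at 3.16-fold [3.07 to 3.25], and SF3B5 3.25-fold [3.09 to 3.42] higher. Ribosome biogenesis genes had one of -0.23 with 4 of 39 lower and 1 higher. These 3 medians lay at or below percentile 0.08.

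Neural genes were lower, 4 of 12 progenitor genes (median -0.75, percentile 0.43) and 3 of 6 neuronal genes (median -0.95, percentile 0.39). They included the transcription factors LHX2 at 4.11-fold [3.02 to 5.69] and ZIC2 at 2.86-fold [2.45 to 3.34] and the synaptic SYT1 at 18.6-fold [13.8 to 25.8]. Both medians were 0 when unexpressed members were kept. Further protein-coding genes with the lowest log2 ratios were the phosphodiesterase PDE4B at 49.6-fold [35.6 to 71.5], SCARA3 at 18.2-fold [13.9 to 24.1] and the mitotic kinesins KIF18B at 14.5-fold [11.8 to 17.9] and KIF20A at 10.7-fold [9.11 to 12.8]. ORC1 at 11.6-fold [9.67 to 14.1] and the nuclear lamin LMNB1 at 8.68-fold [7.78 to 9.70] were among them too.

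Ribosomal protein genes and nuclear genes of oxidative phosphorylation were higher in the PPARG library, while the mitochondrially encoded median was 0.11 at percentile 1.27. All 65 ribosomal protein genes had a positive log2 ratio and 37 were at least 2-fold higher (median 1.11, percentile 99.72), with RPS24 at 3.53-fold [3.44 to 3.62] and RPL31 at 3.41-fold [3.32 to 3.50], though their many pseudogenes can share reads. Of 44 nuclear genes of oxidative phosphorylation 25 were higher and none lower (median 1.08, percentile 99.98), including the cytochrome oxidase subunits COX6C at 4.51-fold [4.27 to 4.78] and COX5B at 4.30-fold [4.07 to 4.55] and NDUFA4 at 4.50-fold [4.26 to 4.77]. In the MYOD1 library the ribosomal protein median was 0.73 (percentile 96.95, 6 of 65 higher). Random lists matched on expression had medians centred on 0.78 in the PPARG and 0.50 in the MYOD1 library for the ribosomal proteins and on 0.51 in the PPARG library for oxidative phosphorylation. The ribosomal protein median of the MYOD1 library lay at percentile 99.58 of random lists also matched on gene length and outside the central 95% under 5 of 11 alternatives. Between the MYOD1 and the PPARG library the ribosomal protein median was -0.46, within the central 95% (percentile 4.74) but outside it under 2 of 11 alternatives. In the MYOD1 library the oxidative phosphorylation median was 0.25 (percentile 26.63), which turned to -0.22 on the TPM scale.

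Interferon-stimulated genes were higher, 15 of 25, with a median of 1.34 above those of all random lists, and with OAS1 at 378-fold [191 to 876], IFI27 at 94.5-fold [57.97 to 166] and ISG15 at 12.3-fold [11.7 to 12.9]. Hypoxia genes were higher (8 of 18, median 0.92, percentile 99.83), with NDRG1 at 9.76-fold [9.32 to 10.2] and ANKRD37 at 10.5-fold [8.16 to 13.6], and so were 6 of 7 histone genes (median 2.27, percentile 99.99). With unexpressed members kept, the histone median and the p53 target median of the PPARG library lay within the central 95%.

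Fatty acid synthesis and cholesterol synthesis had medians of -0.36 (percentile 0.68) and -0.22 (percentile 1.89), with ACACA 2.60-fold [2.47 to 2.75] lower and ELOVL1 5.999-fold [5.72 to 6.30] and FDFT1 2.53-fold [2.46 to 2.61] higher. After length correction both medians lay within the central 95%, at -0.07 and -0.05, and the mean of the cholesterol list was positive, at 0.07.

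The muscle lists lay within the central 95% of random lists in the PPARG library, with medians of -0.17 for regulators (-0.30 with bounds), 0.36 for the sarcomere and 0.02 for membrane genes, the last just below 0 on the TPM scale and on the recovered reads. Of these lists 1 sarcomere gene, TNNC1, and 1 membrane gene, MB, were at least 2-fold higher. Their log2 ratios were 1.09 and 1.77, against 3.30 and 3.35 in the MYOD1 library.

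In all, 270 genes were at least 4-fold higher and 139 at least 4-fold lower in the PPARG library. The balance again depended on the scaling, with 252 higher and 932 lower on the TPM scale, which moves the median of all genes by -0.56, 187 and 214 on the recovered reads, which moves it by -0.20, and 216 and 173 with median-of-ratios factors.

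The medians of the lists not yet given follow. In the MYOD1 and the PPARG library in turn, the medians were -0.19 and 0.11 for the mitochondrially encoded genes (percentiles 0.38 and 1.27, the second below 0 under each other scaling). The first lay within the central 95% after correction for gene length and GC content, and both did so with no filter on low values. The medians were -0.25 and -0.03 for the housekeeping genes (percentiles 0.75 and 1.42, both with positive means and both within the central 95% after length correction). Among housekeeping genes, the tubulin TUBB was 2.53-fold [2.48 to 2.58] and 3.72-fold [3.63 to 3.81] lower and the class I light chain B2M 9.38-fold [9.05 to 9.73] and 7.01-fold [6.75 to 7.27] higher. The medians were 0.55 and 0.26 for the unfolded protein response, 0.50 and 0.60 for immediate early genes, 0.51 and 0.15 for glycolysis, 0.36 and -0.36 for YAP targets and 0.66 and -0.40 for the Notch pathway. The second value turned negative for the unfolded protein response and for glycolysis on the TPM scale and on the recovered reads, and the first turned negative for YAP targets on the TPM scale. All of these 5 lists lay within the central 95% of random lists. In the MYOD1 library the medians were 0.33 for intestinal differentiation, 0.33 for PPAR targets, 0.12 for neural progenitor and 0.33 for neuronal genes, of which the first 3 were negative on the TPM scale and the third also on the recovered reads. In the PPARG library they were 0.46 for the proteasome, 0.23 for heat shock, 0.27 for smooth muscle and 0.31 for mesenchymal genes, all negative on the TPM scale and those of heat shock and smooth muscle also on the recovered reads. For Wnt and stem cell genes the median was -0.22. The mean of the heat shock list was negative, at -0.05. Of the markers of other cell types, 2 endothelial and 3 immune genes reached 1 FPKM. The immune medians were 0.49 and 0.48, both within the central 95%. In MYOD1 against PPARG the immune median was 1.13 at percentile 98.48, with 2 of the 3 genes higher and 1 lower, and it lay within the central 95% after correction for gene length and GC content and was 0 with no filter on low values. Among the genes of both lists were EGFL7 at 4.20-fold [3.94 to 4.48] and 2.35-fold [2.19 to 2.52] above the control and the macrophage receptor CSF1R at 0.0512, 2.83 and 0.469 FPKM in the control, MYOD1 and PPARG libraries. Lysozyme (LYZ) stood at 0.0306, 0.450 and 3.48 FPKM.

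Set directly against each other, the MYOD1 library was higher in muscle genes. The PPARG library was higher in adipocyte and PPAR target genes and in intestinal, ribosome biogenesis and cholesterol synthesis genes. CDH15 was 102-fold [76.9 to 137] higher in the MYOD1 library, JSRP1 250.1-fold [85.2 to 1215], CHRNA1 at least 854-fold and RAPSN, the receptor-clustering protein, 229-fold [40.8 to 9102]. FABP4 was at least 150.4-fold higher in the PPARG library, PLIN4 34.9-fold [23.98 to 52.8] and the hormone-sensitive lipase LIPE 6.36-fold [5.41 to 7.52]. The muscle lists had medians of 1.43 for regulators (1.55 with bounds), 1.47 for membrane genes and 0.79 for the sarcomere, with 7 of 11, 9 of 14 and 5 of 16 members at least 2-fold higher in the MYOD1 library and none lower. The adipocyte median was -0.89 with 8 of 16 lower in the MYOD1 library, the PPAR target median -0.66 with 7 of 23, and the intestinal median -0.95 with 3 of 9. The fatty acid synthesis median of -0.39 lay within the central 95% (percentile 2.85) but outside it under 5 of 11 alternatives.

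G2 and M phase genes were less low in the MYOD1 library, with a median of 0.68 and 14 of 51 at least 2-fold higher than in the PPARG library. The ubiquitin-conjugating enzyme UBE2C stood at 113, 161 and 41.1 FPKM in the control, MYOD1 and PPARG libraries, and the centromere chaperone HJURP at 21.7, 11.1 and 2.90. The S phase median was 0.21, with no member at least 2-fold apart, and it lay within the central 95% when restricted to members of at least 5 FPKM.

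Interferon-stimulated genes had a median of 0.74, with 11 of 25 higher in the MYOD1 library, including IFI6 at 22.3-fold [21.2 to 23.4], and 2 higher in the PPARG library, including OASL at 13.7-fold [12.6 to 14.8]. Medians were lower in the MYOD1 library for ribosome biogenesis (-0.82, 12 of 39 lower, among them GNL3 at 2.92-fold [2.70 to 3.16]) and for oxidative phosphorylation (-0.80, 12 of 44). So were those for the proteasome (-0.70, 6 of 31) and cholesterol synthesis (-0.47, 5 of 25, among them HMGCS1 at 5.67-fold [4.94 to 6.53]). All 4 lay at or below percentile 0.46. They were higher in the MYOD1 library for the Notch pathway (1.09, 7 of 11), for neural progenitor genes (0.74, 5 of 12, led by NES at 69.1-fold [59.3 to 80.98]) and for neuronal genes (1.36, 4 of 6), all at or above percentile 99.76. Medians were also higher in the MYOD1 library for mesenchymal genes (0.91), YAP targets (0.58), cell cycle inhibitors (0.48), Wnt and stem cell genes (0.39) and the unfolded protein response (0.29). They were lower for epithelial genes (-0.40) and histones (-0.97), all outside the central 95% of random lists. Those of the Wnt, epithelial, cell cycle inhibitor and intestinal lists lay within it with members of at least 5 FPKM alone. The Wnt and epithelial medians also did so after correction for gene length and GC content, and the epithelial median with a pseudocount of 5. With unexpressed members kept, the unfolded protein response median lay within it and the mesenchymal, adipocyte, intestinal and neural progenitor medians were 0.

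MYC stood at 107, 24.00 and 121 FPKM in the control, MYOD1 and PPARG libraries.

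The highest log2 ratios among protein-coding genes were those of C6orf15 (1757-fold [686 to 6450.5]), PAEP, PLAU (122-fold [107 to 139]), NES and CDH15. The lowest were those of IGFL2 (522-fold [223 to 1609]), C11orf86 (595-fold [164 to 4917]), S100P (54.4-fold [34.3 to 92.3]), the keratin KRT6A (216-fold [99.1 to 591]) and FABP4. In all, 177 genes were at least 4-fold higher and 62 at least 4-fold lower in the MYOD1 library than in the PPARG library, and 478 and 142 on the TPM scale, which moves the median of all genes by 0.13.

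Part of what differed from the control was higher or lower in both libraries. Of the 384 and 270 genes at least 4-fold higher in the MYOD1 and the PPARG library, 76 were higher in both, among them ISG15, CDKN1A and ANGPTL4, where lists drawn independently would share 8.33. Of the 73 and 139 at least 4-fold lower, 44 were lower in both, among them ORC1, MKI67, ATAD2 and MCM4, where independent lists would share 0.815. These shared counts depend on the processing. Lower in both were 449 genes on the TPM scale and 87 on the recovered reads, and correction for length and GC content gave 50 higher and 29 lower. The pseudocount of 0.1 gave 312 and 255, and that of 5 gave 26 and 6. Both comparisons use the same control library, and unchanged libraries simulated against it shared at most 20 higher and 5 lower genes in 100 runs with an assumed coefficient of variation of 0.4. The simulated lists were shorter than most of those observed. On average 40.8 and 40.7 genes were higher, with 8.61 shared, and 40.6 and 40.1 lower, with 2.25 shared. As a share of the lists, the simulated overlap of higher genes was close to the observed one, and that of lower genes was below it. Across the 12448 genes, which are not independent replicates, the log2 ratios of both comparisons had a Pearson correlation of 0.656, a Spearman correlation of 0.681 and a covariance of 0.571. The simulated unchanged libraries had mean Pearson correlations of 0.464 to 0.498 and covariances of 0.0118 to 0.229. The sign was the same for 76.1% of genes, against 65.3% to 66.6% in the simulations. The single control library could not be split, so part or all of the excess may come from it. No gene was at least 4-fold higher in 1 library and 4-fold lower in the other, and at 2-fold 15 genes were higher with MYOD1 and lower with PPARG and 2 the reverse.

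**Figure D3:**
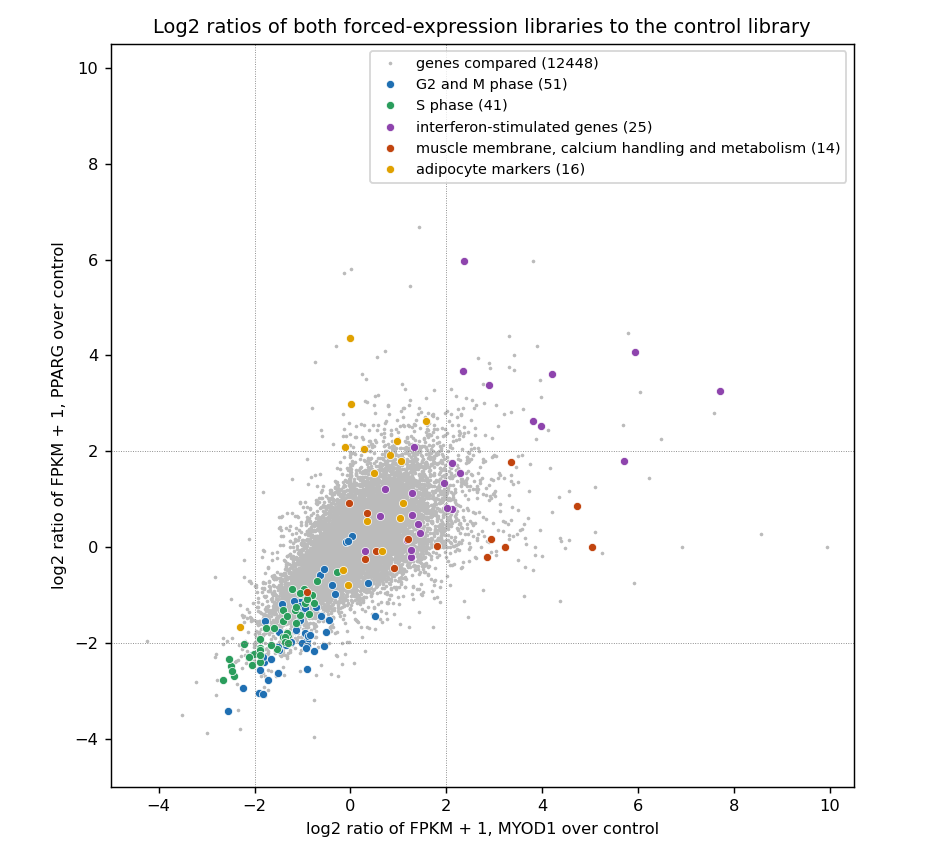
Log2 ratio of FPKM + 1 of the 12448 genes in the MYOD1 library (x axis) and in the PPARG library (y axis) over the control library, 1 point per gene, with members of 5 lists coloured and dotted lines at 4-fold. The S phase and the G2 and M phase genes lie toward the lower left and the interferon genes toward the upper right. Adipocyte genes such as FABP4 lie high on the y axis alone and muscle genes such as CHRNA1 far along the x axis alone.

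The log2 ratios also followed gene length. Over 9913 protein-coding genes with a mean FPKM of at least 1, the Spearman correlation across genes between log2 ratio and gene length was -0.37 in the MYOD1 library and -0.42 in the PPARG library against the control, and 0.06 between both libraries. The shortest 10% of genes had median log2 ratios of 0.73 and 0.88 and the longest 10% -0.46 and -0.48. With transcript GC content the correlations were 0.48, 0.20 and 0.37 in the same order. Reads of mitochondrial tRNA genes numbered 2032 in the control, 13225 in the MYOD1 and 18905 in the PPARG library, and the mitochondrial rRNA genes took 0.577%, 0.765% and 1.65% of reads. After subtraction of the running medians over length and GC content, the S phase medians were -1.33 and -1.88, the interferon medians 2.15 and 1.21, the muscle membrane median 0.98 in the MYOD1 library and the adipocyte median 1.22 in the PPARG library.

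**Figure D4:**
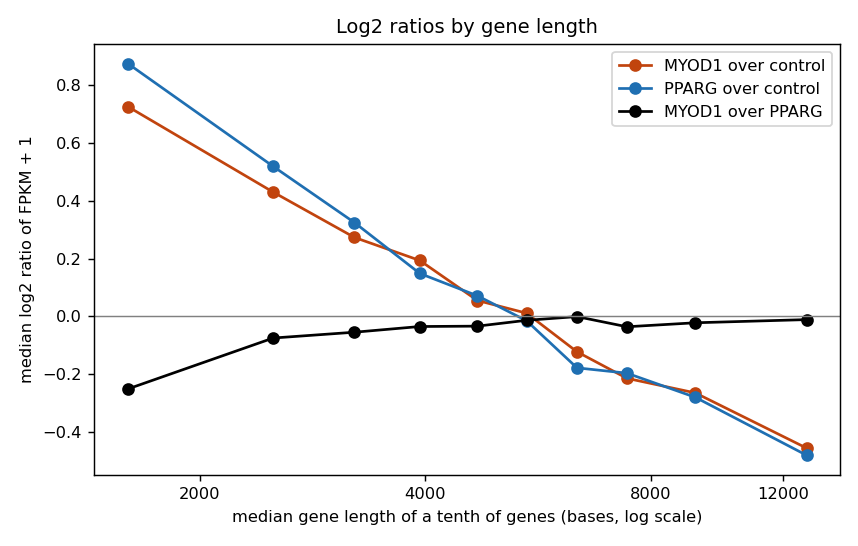
Median log2 ratio of FPKM + 1 (y axis) in 10 equal bins of 9913 protein-coding genes ordered by gene length, placed at the median length of each bin in bases (log x axis). Both ratios to the control decline from 0.73 and 0.88 in the bin of the shortest genes to -0.46 and -0.48 in that of the longest, while the ratio of the MYOD1 to the PPARG library lies between -0.25 and 0.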

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

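The genes and loci in this part were singled out only after the values were seen, and no explanation of them was tested. ACSL5, NES and NOTUM lay in opposite directions in the MYOD1 and the PPARG library by at least 2-fold on the log2(FPKM + 1) scale, among the members of the gene lists. ACSL5, which activates long-chain fatty acids, stood at 29.4 FPKM in the control, 7.59 in the MYOD1 and 66.3 in the PPARG library, with log2 ratios to the control of -1.82 and 1.15 and a difference of -2.97. NES, an intermediate filament of progenitor cells, stood at 5.24, 128 and 1.86 FPKM, with log2 ratios of 4.37 and -1.13 and a difference of 5.50. NOTUM, which inactivates Wnt proteins, stood at 4.56, 67.2 and 1.74 FPKM, with log2 ratios of 3.62 and -1.02 and a difference of 4.64. With 1 library per group these differences were not tested.

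Among the unnamed loci, which entered no comparison, 5 were at least 4-fold above the control in the MYOD1 library and 7 in the PPARG library. The locus at chromosome 3, 5689981 to 5699410, was higher in both, at 2.75, 22.1 and 32.5 FPKM from 222, 1574 and 2232 reads in the control, MYOD1 and PPARG libraries. The locus at chromosome 2, 234285352 to 234289888, had 93 reads in the MYOD1 library and 0 in the others, and that at chromosome 12, 52370530 to 52375360, had 111 reads in the PPARG library and 0 in the others.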

How the results depend on the processing

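The scaling to recovered reads, the corrections for gene length and GC content and the length-matched random lists were chosen only after the result was seen. No paired analysis was possible because each group holds 1 library and no test was run. Across the alternatives, 89 counts stayed within 1.5 times the main count and 36 moved, and 975 list medians stayed within their interval, 85 moved and 17, of lists outside the central 95%, changed sign or were 0. Of lists within the central 95%, 40 further medians did so. For named genes, 1325 alternative ratios stayed within their counting interval and 1482 lay outside it. Among these, 4 had the other sign, all of ratios below 2-fold: PPARG in MYOD1 against control turned from -0.30 to 0.23 and 0.28 after correction for length and for length and GC content, BIN1 in PPARG against control from 0.39 to -0.21 on the TPM scale, and TRIM28 in MYOD1 against PPARG from 0.31 to -0.05 after length and GC correction. Under all 11 alternatives that apply to lists, 15 of 20 medians stayed outside the central 95% in MYOD1 against control, 10 of 20 in PPARG against control and 14 of 24 in MYOD1 against PPARG.

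Counts are given as higher and lower, for MYOD1 against control, PPARG against control, MYOD1 against PPARG and both factors against control, where the main counts were 384 and 73, 270 and 139, 177 and 62, and 76 and 44. The pseudocount of 0.1 gave 1006 and 431, 682 and 595, 620 and 256, and 312 and 255, and the pseudocount of 5 gave 137 and 11, 107 and 21, 58 and 23, and 26 and 6. The 2-fold threshold gave 1958 and 1274, 1815 and 1280, 1124 and 730, and 830 and 790. These settings change the fold that a low gene must reach, by construction. On the TPM scale the lower counts were 681, 932, 142 and 449 and the higher count of MYOD1 against PPARG 478, and scaling to the recovered reads gave 145 lower in MYOD1 against control, 214 in PPARG against control and 87 in both. By construction these scalings multiply each library by its own factor, and on the TPM scale values are also larger relative to the pseudocount. Correction for length and GC content gave 251 higher in MYOD1 against control and 50 higher and 29 lower in both, and the cause was not tested.

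With no filter on low values, 13 list medians instead of 20 lay outside the central 95% in PPARG against control. Medians then were 0 for the skeletal muscle regulators in MYOD1 against control, for the adipocyte, intestinal, neural progenitor and neuronal lists in PPARG against control, and for the mesenchymal, adipocyte, intestinal, neural progenitor and immune lists in MYOD1 against PPARG. This is because members under 1 FPKM in every library, many of them without a read, then enter the list. The housekeeping median turned to 0.0115 in MYOD1 against control and 0.0315 in PPARG against control after length correction, and the cause was not tested. The mitochondrially encoded median in PPARG against control, 0.11, turned to -0.54 on the TPM scale, -0.0321 with median-of-ratios scaling, -0.17 on the recovered reads, -0.38 after length correction and -0.22 after length and GC correction, and the cause was not tested. Depth limits low genes most, since 1 read on a gene of 1 kb is worth 0.0527 to 0.0619 FPKM.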

Other observations

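Among the tests reported here, those that set the MYOD1 library against the PPARG library to examine the control library alone were chosen only after the result was seen, as were the gene families, of which 14 were examined. The corrections for gene length and GC content were also added after seeing the data.

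Among the families examined, the kallikreins, keratins and S100 proteins had medians above the central 95% of random lists matched on expression in both forced libraries. All 7 measured kallikreins, a family of secreted proteases, were at least 2-fold higher in the MYOD1 library and 5 in the PPARG library (medians 2.99 and 1.93), with KLK6 at 19.9 FPKM in the control against 322 and 233. Of 17 keratins 11 and 12 were higher (medians 1.68 and 1.12), with KRT80 at 3.58 FPKM against 71.4 and 39.1. Of 11 S100 calcium-binding proteins 9 and 10 were higher (medians 1.55 and 2.12). Of 13 serpins, a family of protease inhibitors, 9 were higher in the MYOD1 and 4 in the PPARG library (medians 1.48 and 0.37, percentiles 100 and 86.2). Of 7 claudins, proteins of tight junctions, 3 and 4 were higher (medians 0.78 and 1.09, percentiles 93.47 and 98.66), and both medians lay within the central 95% of random lists also matched on gene length (percentiles 88.98 and 97.06). The HLA class I genes, which present antigen, were higher in the MYOD1 library in all 5 cases (median 3.12, percentile 100) and in 4 in the PPARG library (median 1.18, percentile 88.62), with HLA-B at 23.4, 319 and 54.01 FPKM in the control, MYOD1 and PPARG libraries. Reads of such near-identical families can be shared between members.

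Other families differed between the forced libraries or were lower. Of 72 mitochondrial ribosomal proteins 26 were at least 2-fold higher in the PPARG library and 3 in the MYOD1 library (medians 0.73 and -0.08). The median in the MYOD1 library lay below the central 95% of random lists matched on expression (percentile 0.39, and 0 when these were also matched on gene length). That in the PPARG library lay at percentile 99.89 of the first, but at 85.41, within the central 95%, of the second. All 4 measured aldo-keto reductases were higher in the PPARG library and 2 in the MYOD1 library (medians 2.05 and 0.97, percentiles 99.98 and 95.61), with AKR1C3 at 0.175 FPKM in the control, 2.09 in the MYOD1 and 3.51 in the PPARG library. Of 21 nucleoporins 13 and 9 were lower in the MYOD1 and the PPARG library (medians -1.09 and -0.88), and of 30 kinesins 13 and 15 were lower and 5 and 0 higher (medians -0.90 and -0.98). None of these families' medians against the control changed sign under the 3 other scalings.

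The log2 ratios to the control were lower the longer the gene, in both forced libraries. Of the 9913 genes 9185 were in no list, so the listed genes were too few to set the trend. The genes in no list had a Spearman correlation with length of -0.37 in the comparison where it was weaker. Leaving out so few genes could hardly change the correlation, and it does not bear on gene groups outside the lists. Between the MYOD1 and the PPARG library the correlation was 0.0583, and 0.157 with GC content held constant, which does not bear on the trend that both share. A feature of the only control library, such as RNA quality or library preparation, and a response common to both forced libraries would each give that shared trend and cannot be told apart with 1 control library.

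The S phase and the G2 and M phase lists were low and the interferon list was high in both forced libraries. The trend with gene length and GC content does not account for it, since after correction the medians nearest 0 were -1.33, -0.89 and 1.21. The MYOD1 library was 0.21 above the PPARG library in the S phase median, 0.68 in the G2 and M phase median and 0.74 in the interferon median, gaps that either forced library could give and that do not bear on what both share. For each of the 3 lists a feature of the only control library and an effect common to both forced libraries cannot be told apart, since both leave the same shared difference from the control. The forced factors, cell density and the viral constructs remain open and were not tested, since no group has a second library.

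The ribosomal protein and oxidative phosphorylation lists, with median gene lengths of 3461 and 2663.5 bases, were high in the PPARG library. The trend with gene length and GC content does not account for all of it, since the corrected medians were 0.88 and 0.77, from 1.11 and 1.08 before. Random lists matched on expression had medians centred on 0.78 and 0.51 before correction, a part that genes of like expression share. Forced PPARG and a feature of the PPARG library itself, in which mitochondrial rRNA also took a larger share of reads, both stay open and were not tested.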
